A study of Mus musculus with 8 samples.

How the data were processed

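RNA of naive CD4 T cells from wild-type mice (4 samples) and from mice with a T cell-specific deletion of Bcl6 (4 samples) was hybridised to 8 arrays, 1 sample each. Per the labels' protocols, sorted cells were stimulated for 24 hours with antibodies to CD3 and CD28, RNA was isolated with a column kit, and 100 ng of total RNA was labelled with biotin by the manufacturer's whole-transcript protocol. The values deposited by the authors are log2 signals, 1 per transcript cluster and array. Per the submitters' processing notes, RMA and Partek were used. RMA corrects background, brings all arrays to 1 distribution and combines the probes of a cluster, which lowers differences of dim genes. Versions and settings are not given in the sources used here. The log base follows from the range of the values and from RMA, which works in log2.

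The table has 35556 clusters. The platform annotation used here gives 1 gene symbol to 21789 of them, several to 1621 and none to 12146. Only clusters with 1 symbol were named. Where a gene had several clusters (999 genes), the one with the highest mean signal over the 8 arrays was kept, which left 19938 genes. Chromosomes and gene order came from a RefSeq table of GRCm38.p6, matched through the Entrez ID (21698 of the 21789 clusters). No coordinates are given, since the array values name no genome build. No column of sample values was left unused.

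Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on the deposited log2 values, with 1 estimate of the spread over both groups and no covariate. Log2 differences are Bcl6 cKO minus wild type, and p-values were adjusted by Benjamini and Hochberg over all genes tested, at a threshold of 0.05. No filter on dim genes was applied. Bcl6 was also tested by a two-sided exact permutation test of its 8 values. With 4 against 4 arrays the smallest p such a test can give is 0.0286.

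A total of 27 gene lists, with 492 entries of which 445 matched a tested gene, were fixed from textbook knowledge. They cover helper T cell programs, Bcl6 targets, activation, metabolism, survival, cell cycle, markers of other cells, sex-linked genes and the neighbours of Bcl6. Entries without a match were not analysed here. The glycolysis entry Gpi1 was matched through a synonym to Pigq, a different gene, which stayed in that list. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 27 lists. Camera with an estimated correlation and fry were the alternatives. Fry asks whether a list's own genes move, on balance, one way, and does not compare them with other genes.

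The design, the lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule names Bcl6. Per direction it takes the 10 genes with the largest log2 difference among those past the threshold whose groups are separate, and for each list the 3 members with the smallest p, or up to 6 where more than 3 passed. A direction with fewer than 5 genes past the threshold would have been filled up to 10 by unadjusted p, which did not arise. Predicted models, clones, small RNA genes, olfactory and vomeronasal receptors, pseudogenes and antigen receptor segments are only counted. This left out 5 of the 44 genes, including B4galt4, whose name has the form of a clone name. B4galt4 is reported all the same, picked after its value was seen.

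Other settings fixed at that time were variance moderation with trend and robust options, array weights, median centring, quantile normalization, 2 filters on mean signal (the 30th percentile and the median), the mean of a gene's clusters, the replicate number as a block, leaving out each array, 1 surrogate variable, and 2 other thresholds. The fit with a surrogate variable is not reported, since its package could not be used in the final run, and the first principal component of the residuals took its place after the data were seen. Also added after seeing the data were sex, read from the Y-linked genes, as a term; odd or even replicate number as a term; both together; the difference within each sex; and counts without chromosome 16 or without chromosomes X and Y. The analysis of chromosome 16 was also added after the data were seen.

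The steps were tested on simulated data for the same comparison, with 200 of 19938 genes changed in 20 simulations. Limma recovered 94.9% of genes changed by 0.5 on the log2 scale, 99.6% at 1 and 100% at 2, and 5.32% of its calls were false. A list shifted by 0.3, the proliferation list, was called in 100% of simulations. Simulated genes varied independently of each other, with no difference by sex or replicate number. In the deposited values the proliferation list had an estimated correlation of 0.68, so these rates need not hold there. In the deposited values the median standard error of a log2 difference was 0.065. Any pair of arrays had identical values in at most 3.94% of genes, so none was a copy of another.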

Results

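Gene expression was measured on 8 Affymetrix whole-transcript arrays of mouse naive CD4 T cells, the antigen-inexperienced helper T cells of the immune system. The cells were sorted from wild-type mice (n = 4) and from mice that lack Bcl6 in T cells only (n = 4, called Bcl6 cKO here). Bcl6 is a transcriptional repressor best known for directing the differentiation of follicular helper T cells. Before RNA isolation the cells were activated for 24 hours with antibodies to CD3 and CD28, which stand in for antigen and costimulation. The labels add the tag Tf0, whose meaning they do not give. Arrays have no read depth, so the number of arrays limits the precision. The median log2 signal of the 19938 genes tested lay between 7.57 and 7.64 on the 8 arrays, and the correlation between any pair of arrays, across genes, was 0.994 or higher. Nothing in the labels says which samples came from separate mice, so p-values measure the spread between these samples.

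The deleted gene came first, since it can check the genotype labels where its probes cover the deleted exons. The signal of Bcl6 was 8.37 ± 0.20 (log2, mean ± SD, n = 4) in wild type and 8.74 ± 0.27 (n = 4) in Bcl6 cKO, a log2 difference of 0.37 with a 95% confidence interval of 0.075 to 0.67. It was therefore not lower on the arrays labelled knockout, and the difference did not pass a two-sided exact permutation test (p = 0.0857, smallest possible 0.0286) or limma over all genes (adjusted p = 0.337). The array reads Bcl6 through 1 transcript cluster, and the labels do not state which exons were removed. A transcript that keeps its undeleted exons would still be read, so this signal checks nothing about the labels, and Bcl6 cKO below means the arrays labelled knockout.

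The comparison asks which genes Bcl6 controls in activated naive CD4 T cells. In Bcl6 cKO the membrane carboxypeptidase gene Cpm rose 4.10-fold, from 8.03 ± 0.37 to 10.06 ± 0.41 (log2, SD, n = 4 each). The chemokine gene Ccl3 rose 3.11-fold, from 10.18 ± 0.41 to 11.82 ± 0.34, the inflammatory cytokine gene Il1a rose from 5.36 ± 0.22 to 6.74 ± 0.50 and the autophagy protease gene Atg4c from 5.60 ± 0.31 to 6.84 ± 0.26. No fold is given for Il1a and Atg4c, whose wild-type means lay within the range of the Y-linked genes Kdm5d, Uty and Eif2s3y on the 4 arrays with high Xist (4.58 to 5.83) and so were not shown to stand above background. Smaller rises than that of Ccl3 were found for the carboxypeptidase Cpd (2.33-fold), the LIM-domain gene Lpp (1.99-fold) and Nrp1, a surface receptor also used as a marker of thymus-derived regulatory T cells (1.76-fold). Ift57, which encodes an intraflagellar transport protein, rose 1.60-fold, Neb (nebulin) 1.52-fold and Sbf2 1.51-fold.

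Among the genes that fell past the threshold over all genes, Trim12a changed most, by 2.10-fold, from 9.38 ± 0.38 to 8.31 ± 0.15. The ubiquitin ligase gene Neurl3 was 1.91-fold lower. Atp1b1, a subunit of the sodium-potassium pump, fell 1.86-fold from 11.30 ± 0.10 to 10.41 ± 0.16. The kinesin gene Kif1b was 1.83-fold lower and Wls, needed for Wnt secretion, 1.71-fold lower. Il10ra, which encodes the ligand-binding chain of the interleukin-10 receptor, fell 1.55-fold. Ndrg1 fell 1.53-fold, with SDs of 0.07 and 0.06 on means of 9.69 and 9.07. Dubr, a long non-coding RNA gene, was 1.44-fold lower, the innate immune regulator Nlrc3 1.39-fold lower and the beta-arrestin gene Arrb1 1.38-fold lower. Adjusted p-values of these named genes (limma) ran from 0.0031 for Atp1b1 and Ndrg1 to 0.0461 for Neurl3 and Wls.

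**Figure D1:**
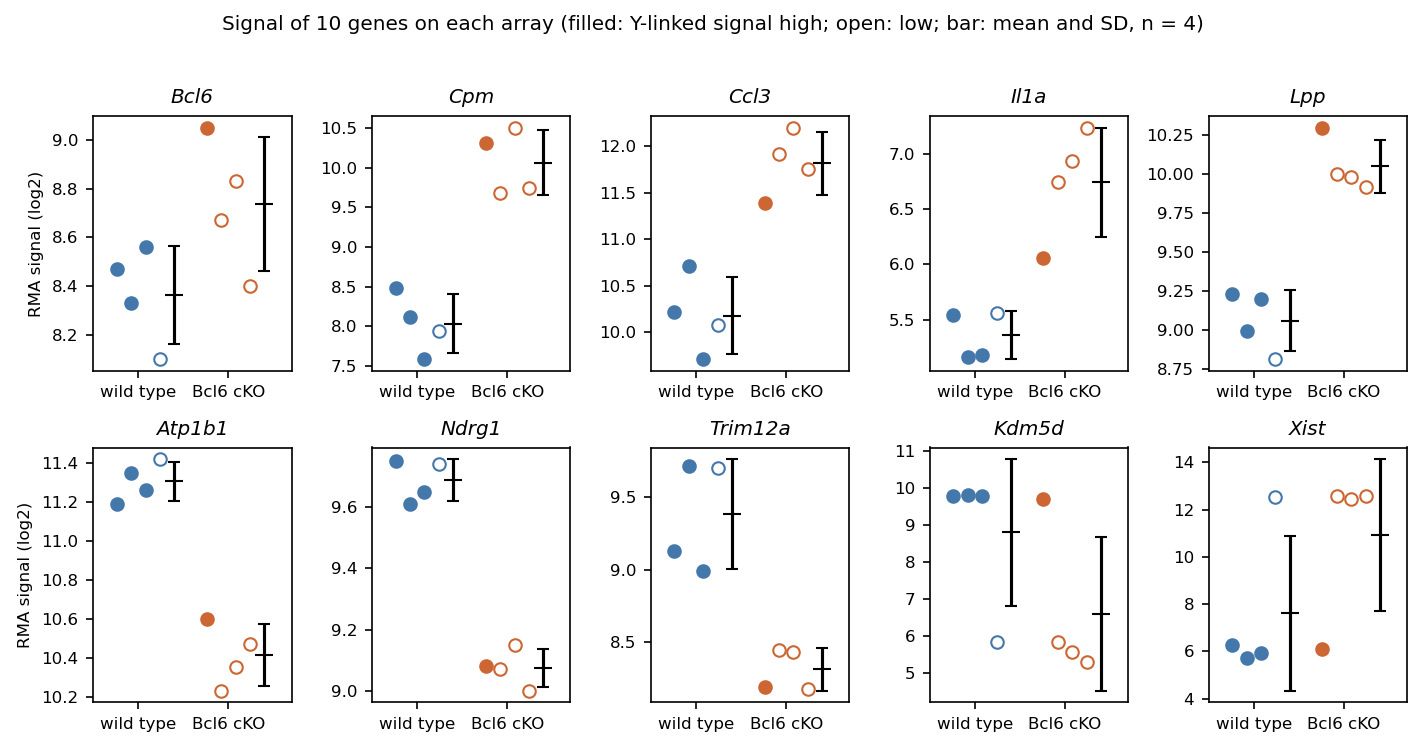
RMA signal (log2) of 10 genes on each array, in wild type (blue) and Bcl6 cKO (orange), with the mean and SD of each group (n = 4) as a black bar beside the points. Filled points are arrays with a high signal of Y-linked genes. The groups do not overlap for Cpm, Ccl3, Il1a, Lpp, Atp1b1, Ndrg1 and Trim12a, and they overlap for Bcl6, Kdm5d and Xist.

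In all, 44 of 19938 genes passed an adjusted p of 0.05 in limma, 21 higher and 23 lower in Bcl6 cKO. With the replicate number as a block 23 of the 44 passed; of the genes named so far, Nrp1, Neb, Sbf2, Neurl3, Dubr, Nlrc3 and Arrb1 did not. Of the 44, 7 differed at least 2-fold on the values as given, 6 of them higher, Il1a and Atg4c included. The groups of all 44 genes were fully separate, which their choice by a small p makes likely, so it is no further evidence. Over all genes 1190 (5.97%) had separate groups. Chance gives 2.86% on average over splits of the arrays into equal groups, but genes vary together, so a given split can lie far from it. Separate groups were not counted in other splits, so whether 5.97% exceeds chance was not tested. Without adjustment, 2164 genes had a p under 0.05. The balance of directions moved with the scaling. After centring each array on its median 19 genes were higher and 13 lower, and after quantile normalization 22 were higher and 14 lower.

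The sex of the mice is not given by the labels and differed between the groups. The Y-linked genes Kdm5d and Uty were high, and the X-inactivation RNA Xist low, on 3 wild-type arrays and 1 Bcl6 cKO array, and the reverse held on 1 wild-type and 3 Bcl6 cKO arrays. With sex added to the fit, 5 genes were higher and 5 lower, all 10 among the 44. Cpm, Lpp, Ift57, Sbf2, Atp1b1, Kif1b and Ndrg1 were among these, and Ccl3, Il1a and Il10ra no longer passed (adjusted p = 0.0942, 0.0887 and 0.146). The log2 differences of the 44 genes were then a median of 0.934 times those without sex, with a range of 0.787 to 1.22. Within the arrays with high Y-linked signal no gene passed in limma (852 at an unadjusted p under 0.05), and within the others 32 genes were higher and 11 lower (3927 unadjusted). Each of those comparisons sets 1 array of a genotype against 3, so the lone array is assumed to vary like the rest. The lone wild-type array among the others, replicate 4, did not look like the rest. Its deviations from each gene's median had an interquartile range of 0.18, against 0.085 to 0.115 on the other 7 arrays, and its estimated array weight was the lowest of the 8 (0.367, next 0.759). The counts within these arrays rest on it. The unequal counts therefore do not show that the genotype difference is unequal between the sexes. All 44 genes kept their sign within both sexes, which their choice by the pooled difference makes likely.

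Leaving out any 1 array changed both counts by more than 1.5 times, to between 5 and 39 genes higher and between 5 and 100 lower. Without wild-type replicates 1 to 4 the counts higher and lower were 6 and 5, 9 and 9, 8 and 10, and 7 and 5. Without Bcl6 cKO replicates 1 to 4 they were 39 and 100, 12 and 10, 5 and 6, and 6 and 5. Cpm, Lpp, Ift57, Atp1b1 and Ndrg1 passed in all 8 of these fits. Ccl3, Atg4c and Kif1b passed in 4 of the 8, Sbf2 and Trim12a in 2, and Il1a, Cpd, Nrp1, Neb, Neurl3, Wls, Il10ra, Dubr, Nlrc3 and Arrb1 in 1.

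Genes past the threshold were concentrated on chromosome 16, which carries Bcl6. It held 11 of the 44 genes (25.0%), against 3.25% of the genes tested (one-sided Fisher's exact test over 22 chromosomes, odds ratio 10.1, adjusted p = 2.5e-06). In the gene order of GRCm38.p6, counted in tested genes, Lpp is the next gene after Bcl6, and 10 of the 11 lay among the 200 genes after it. Of these 10, 5 were higher (Lpp, Bdh1, B4galt4, Cd200 and Ift57) and 5 lower (Hspbap1, Slc35a5, Plcxd2, Dubr and Cep97). B4galt4, a galactosyltransferase gene, had the smallest adjusted p of all genes (0.0014) and rose from 7.43 ± 0.15 to 8.68 ± 0.17 (n = 4 each). It and the others of this paragraph that no earlier paragraph names were picked after their values were seen, except Cd200. Without chromosome 16, 16 genes were higher and 17 lower.

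**Figure D2:**
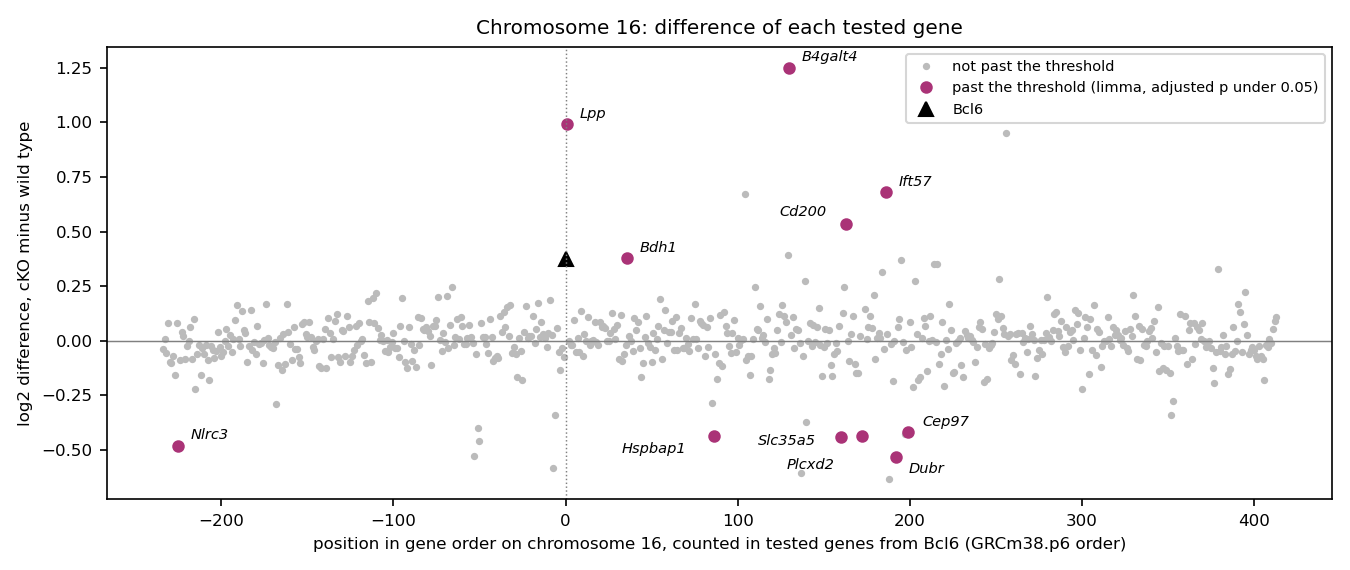
Log2 difference (Bcl6 cKO minus wild type) of each tested gene of chromosome 16 against its place in the gene order, counted from Bcl6 (black triangle). Purple points passed an adjusted p of 0.05 in limma. Of these 11 genes, 10 lie between 1 and 199 genes after Bcl6, and Nlrc3 lies 225 genes before it.

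The genes known for follicular helper T cells, fixed as a list beforehand, did not move together. Of 25 measured members, 11 were above and 14 below wild type, with a mean log2 difference of 0.01 and a median of -0.02 (camera adjusted p = 0.758). Cd200, which encodes a surface ligand, was the 1 member past the threshold over all genes and rose 1.45-fold. It passed in 2 of the 8 fits without 1 array, and did not pass with sex in the fit (adjusted p = 0.169) or with the replicate block (adjusted p = 0.0575). Adjusted over the list alone, Il6st, the shared receptor chain of the interleukin-6 family, also fell (log2 difference -0.23). The chemokine receptor Cxcr5 was 6.95 ± 0.33 in wild type and 6.48 ± 0.16 in Bcl6 cKO (n = 4 each), and did not pass (adjusted p = 0.257).

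Of 25 measured proliferation genes 24 were above wild type, with a mean log2 difference of 0.25 (camera adjusted p = 3.77e-07 with the preset correlation, and adjusted p = 0.71 with an estimated correlation). No single member passed over all genes or adjusted over the list alone. Top2a, the DNA topoisomerase of dividing cells, had a log2 difference of 0.45 (adjusted p = 0.226), Ccne2 (cyclin E2) 0.49 and the mitotic kinase Bub1 0.58. The 2 groups of array means did not pass a two-sided exact permutation test (p = 0.143). Within the arrays with high Y-linked signal the mean difference was 0.04, and within the others, with replicate 4 as the lone wild-type array, 0.50.

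Of 15 naive and quiescent T cell genes 13 were below wild type, with a mean log2 difference of -0.17 (camera adjusted p = 0.0033, and adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone 5 genes fell and 1 rose. Those that fell included the antiproliferative gene Btg2 (log2 difference -0.49) and the transcription factor Lef1 (-0.23), and Dapl1 rose (0.57). None of the 15 passed over all genes. The mean difference was -0.01 within the arrays with high Y-linked signal and -0.31 within the others, with replicate 4 as the lone wild-type array. The list passed with sex in the fit (adjusted p = 0.0439, and adjusted p = 0.941 with an estimated correlation) and not with sex and odd or even replicate number (adjusted p = 0.068).

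Chemokine genes were higher as a group in the main fit. Of 17 measured ligands 13 were above wild type (mean log2 difference 0.25, camera adjusted p = 0.0198, and adjusted p = 0.71 with an estimated correlation). The list did not pass without wild-type replicate 3 or without Bcl6 cKO replicate 2. The list mean of the latter was 7.52, against 6.94 to 7.22 on the other knockout arrays. The mean difference was 0.02 within the arrays with high Y-linked signal and 0.30 within the others, with replicate 4 as the lone wild-type array. Ccl3 passed over all genes. Ccl4, a related chemokine gene, was also higher adjusted over the list alone (log2 difference 0.76), and Ccl17 did not pass (0.28). With sex in the fit this list no longer passed (adjusted p = 0.451), and with sex and odd or even replicate number it did (adjusted p = 0.0257, and adjusted p = 0.8288 with an estimated correlation). Ccl3 and Ccl4 were also among the 3 genes of the Th1 and cytotoxic list that rose adjusted over the list alone, with Il12rb1, a chain of the interleukin-12 receptor (0.30). That list of 20 genes had 12 members above wild type and did not pass as a whole (adjusted p = 0.0941). It passed at the preset correlation with the replicate block (adjusted p = 0.0276, and adjusted p = 0.689 with an estimated correlation), with odd or even number (adjusted p = 0.034, and adjusted p = 0.578 with an estimated correlation) and with sex and odd or even number (adjusted p = 0.00264, and adjusted p = 0.8288 with an estimated correlation).

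Trafficking receptors known to be bound or repressed by Bcl6 were shifted down. Of 18 measured members 11 were below wild type, with a mean log2 difference of -0.11 (camera adjusted p = 0.0389, and adjusted p = 0.71 with an estimated correlation). None passed over all genes and 5 fell adjusted over the list alone. These included Selplg, which encodes the selectin ligand PSGL-1 (log2 difference -0.33), the integrin chain Itga4 (-0.48) and the chemokine receptor Cxcr4 (-0.37). The trafficking list did not pass without wild-type replicate 2 or 4, or without Bcl6 cKO replicate 1 or 3. Its array means ran from 8.56 to 9.01 in Bcl6 cKO and from 8.76 to 8.92 in wild type. The mean difference of odd from even replicate numbers, -0.22, was larger than that of genotype. Of 16 transcription factors repressed by Bcl6, 9 were above wild type (adjusted p = 0.716). Adjusted over the list alone 2 rose and 3 fell, among them Bhlhe40 (0.29), Klf2 (-0.63) and the helper lineage factor Zbtb7b (-0.20).

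The list for amino acid supply and unfolded protein stress was shifted up. Of 20 members 14 were above wild type (mean log2 difference 0.11, camera adjusted p = 0.0389, and adjusted p = 0.71 with an estimated correlation). The stress-induced transcription factor Atf3 (1.03) and asparagine synthetase Asns (0.50) rose adjusted over the list alone, and Sdf2l1 did not (0.20). It no longer passed with sex in the fit (adjusted p = 0.0551) or with the replicate block (adjusted p = 0.0569), and passed with sex and odd or even number (adjusted p = 0.00702, and adjusted p = 0.8288 with an estimated correlation). The list also did not pass without wild-type replicate 3 or 4, or without Bcl6 cKO replicate 2 or 4. Nor did it pass with array weights, with either filter on mean signal or with the first principal component of the residuals. Its mean was -0.07 within the arrays with high Y-linked signal and 0.27 within the others. Th17 genes were shifted up by a mean of 0.13, with 10 of 12 above wild type (adjusted p = 0.0433, and adjusted p = 0.71 with an estimated correlation). None passed alone, Ahr had a log2 difference of 0.41 and Batf 0.17, and with sex in the fit the adjusted p of the list was 0.748. The Th17 list did not pass without wild-type replicate 1, wild-type replicate 3 or Bcl6 cKO replicate 2. The list mean of the last was 7.35, against 6.94 to 7.12 on the other knockout arrays. The lists called shifted or higher so far were the 6 of 27 past the threshold. With an estimated correlation none of the 27 passed, nor had any an unadjusted p under 0.05, and with fry none passed and 1 had an unadjusted p under 0.05. With the replicate block, sex, odd or even number, or sex and odd or even number in the fit, 7, 4, 8 and 6 lists passed at the preset correlation. None passed in these 4 fits with an estimated correlation (none unadjusted) or with fry (1, 0, 1 and 0 lists at an unadjusted p under 0.05). After quantile normalization 2 lists passed, proliferation and naive T cell genes.

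**Figure D3:**
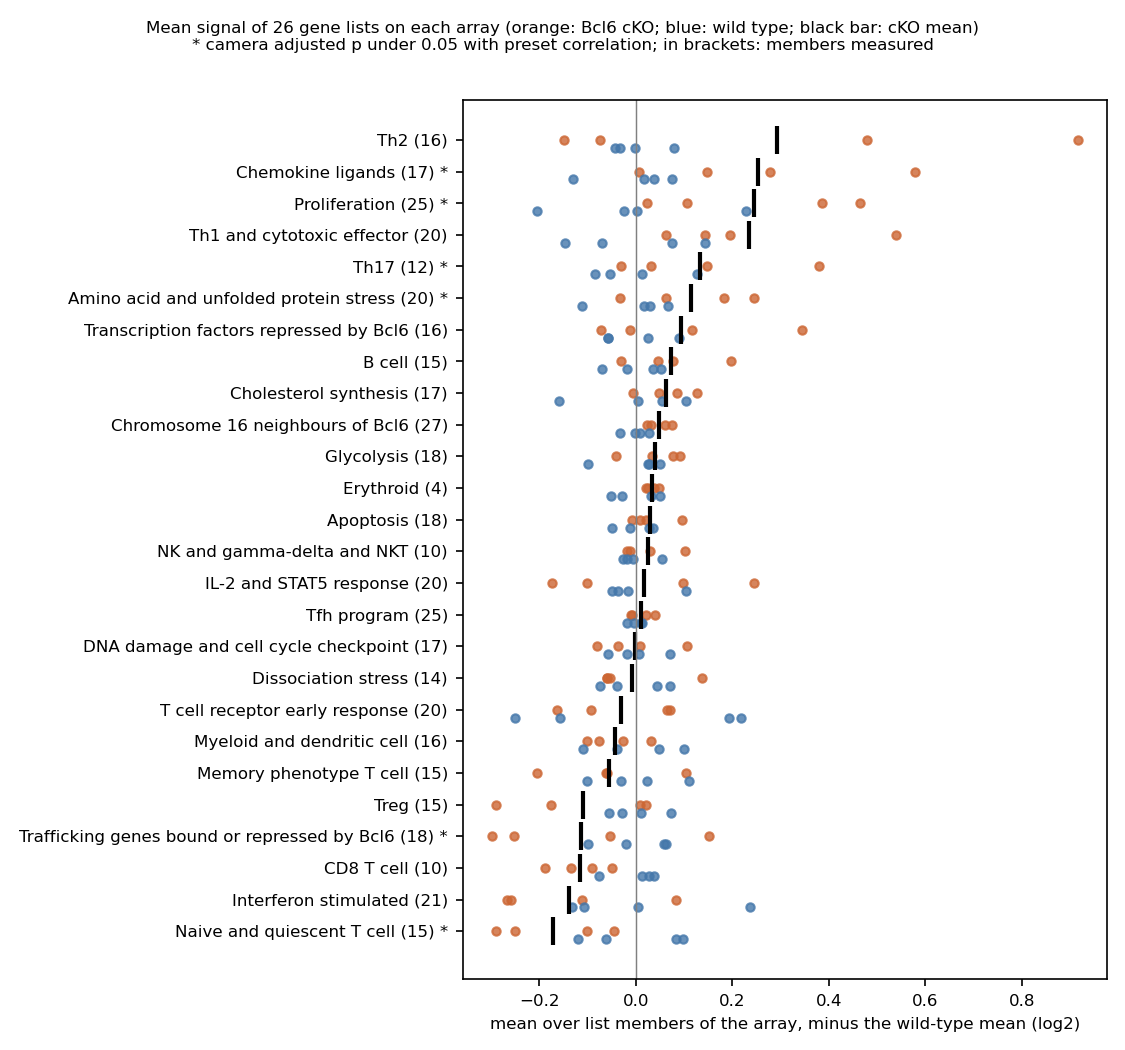
Mean log2 signal of the measured members of 26 gene lists on each array, as the difference from the wild-type mean (orange, Bcl6 cKO; blue, wild type; black bar, Bcl6 cKO mean). Asterisks mark the 6 lists with a camera adjusted p under 0.05 at the preset correlation. The arrays of both groups overlap in each of these 6 lists.

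The other functional lists did not pass. Th2 genes had a mean log2 difference of 0.29 with 12 of 16 above wild type (adjusted p = 0.0937). With odd or even number in the fit the list was at the threshold (adjusted p = 0.049998, and adjusted p = 0.578 with an estimated correlation). Among them the cytokine gene Il3 stood at 6.88 ± 0.44 in wild type and 9.11 ± 1.82 in Bcl6 cKO (n = 4 each), a spread too wide to pass (adjusted p = 0.265). Ecm1 (-0.89) did not pass either, nor did Il10, whose means of 5.19 and 5.66 were not shown to stand above background. Genes of the early T cell receptor response were spread to both sides (8 of 20 above, mean -0.03, adjusted p = 0.589), with Il2 at 0.57, Myc at 0.17 and Nfkbid at -0.24. Targets of interleukin-2 signalling had a mean of 0.02, a median of -0.03 and a test that pointed down (adjusted p = 0.716), and Gzmb was 0.60 higher without passing. Interferon-stimulated genes had a mean of -0.14 with 15 of 21 below wild type (adjusted p = 0.245). With the replicate block the list passed at the preset correlation (adjusted p = 0.00969, and adjusted p = 0.689 with an estimated correlation), and it did not with sex (adjusted p = 0.451) or with sex and odd or even number (adjusted p = 0.954). Ifit1 (-0.76), Ifit2 (-0.37) and Ifit3 (-0.41) did not pass, and Ifit1 did with the replicate block (adjusted p = 0.0223).

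Metabolic and survival lists did not pass in the main fit either. Cholesterol synthesis had a mean of 0.06 (12 of 17 above, camera adjusted p = 0.056), with Idi1 at 0.17. With sex in the fit it passed at the preset correlation (adjusted p = 0.00403, and adjusted p = 0.941 with an estimated correlation). It also passed with sex and odd or even number (adjusted p = 0.0040, and adjusted p = 0.8288 with an estimated correlation). The same held at the preset correlation when wild-type replicate 1, 2 or 3, or Bcl6 cKO replicate 1 or 3, was left out. Glycolysis, with the mismatched Pigq among its 18 members, had a mean of 0.04 (adjusted p = 0.254), and apoptosis 0.03 (adjusted p = 0.563). DNA damage and cell cycle checkpoint genes had a mean just below 0 and a median of 0.05, with the test pointing up (adjusted p = 0.833). Dissociation stress genes averaged -0.01 with a median of 0.04 and a test that pointed up (adjusted p = 0.926). The neighbours of Bcl6 on chromosome 16 averaged 0.05 (17 of 27 above, adjusted p = 0.254). Of these Lpp rose over all genes and St6gal1 (-0.34) fell adjusted over the list alone.

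Markers of other cells did not pass as groups in the main fit. The CD8 T cell list did pass at the preset correlation among genes above the median of mean signal. Regulatory T cell markers averaged -0.11 with 10 of 15 below wild type (adjusted p = 0.245). Nrp1 rose, whereas Gpr83 (-1.20) and the lineage factor Foxp3 (-0.50) were among 3 that fell adjusted over the list alone. CD8 T cell markers averaged -0.12 (7 of 10 below, adjusted p = 0.199), and Cd8b1 (-0.47) fell adjusted over the list alone, as did Klrd1 (-0.49), whose means of 5.73 and 5.24 were not shown to stand above background. Memory T cell markers averaged -0.06 (adjusted p = 0.254), but Cd44 (0.82) and Itgb1 (0.30) rose adjusted over the list alone. Myeloid markers averaged -0.04 (adjusted p = 0.405), with Fcgr3 (-0.32) lower adjusted over the list alone. B cell markers averaged 0.07 (adjusted p = 0.254), natural killer, gamma-delta and NKT markers 0.02 (adjusted p = 0.833) and erythroid markers 0.03 (4 members, adjusted p = 0.483). Of 4 sex-linked genes 3 were below wild type, with a mean of -1.05 (adjusted p = 0.254).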

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

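The tests of chromosome 16, of the sex imbalance and of the genotype labels were chosen after the results they bear on were seen. The tests of other splits of the arrays and of the Bcl6 probes were planned.

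The first pattern is the concentration of changed genes on chromosome 16, with 11 of 44 genes. A candidate explanation is a variant of another mouse strain carried along with the targeted Bcl6 allele, and it was tested in 2 forms. A narrow segment centred on Bcl6 was argued against. The median distance of the 11 genes from Bcl6 was 163 tested genes, and a share of 0.51 of 10000 random draws from the chromosome was as close. A segment spanning much of the chromosome would give such a distance too, so this test cannot decide on it. Of the 400 genes within 200 of Bcl6 on either side 10 were called, against 1 of the other 247. None of the 200 genes before Bcl6 was called. A segment with Bcl6 at its edge was written down only after the median distance had gone against a centred one. As first run it used a window of 200 genes, chosen when the 199th gene after Bcl6 was known to be the last one called. Over 5 window sizes the best window held more called genes than random draws (share 0.0025 of 2000 draws). Windows of 50, 100 and 150 genes showed no excess (shares 0.456, 0.56 and 0.615), and those of 200 and 300 did (0.0015 and 0.0185). Sex as the whole cause was argued against, since with sex in the fit 5 of the 10 genes past the threshold lay on chromosome 16 (one-sided Fisher's exact test, p = 7.86e-06). A strain segment at one side of Bcl6, a wide segment around it and an effect of Bcl6 on these genes all stay open. The breeding history that would part them is not in the labels.

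The second pattern is the Bcl6 signal, which was not lower on the arrays labelled knockout (log2 difference 0.37). A single wrong genotype label was argued against. Each array was placed between the group means by 50 genes chosen without it, and all 8 lay nearer to their own label. On a scale from 0 (wild type) to 1 (knockout) they lay at 0.030 to 0.22 for wild type and 0.60 to 1.05 for Bcl6 cKO. The 0.60 was that of replicate 1, the 1 knockout array with high Y-linked signal, and the next was 0.87. Wild-type replicate 4, the 1 wild-type array with low Y-linked signal, lay at 0.036. For the other arrays the score can also follow sex. Probes outside the deleted exons cannot be told apart from a lack of deletion, because the values hold 1 cluster for Bcl6 and the labels name no exons.

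The third pattern is the higher mean of the proliferation genes in Bcl6 cKO (0.25 on the log2 scale). With sex in the fit the shift was 1.09 times as large (0.27), but its 95% interval over the arrays ran from -0.18 to 0.72, so a part of sex cannot be told apart here. Chance could not be excluded either, since 5 of the 35 splits of the 8 arrays gave a shift as large, the highest of the others being 0.35. A biological difference between the genotypes stays open.

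Other splits of the arrays bear on the counts. Genes higher (21) were matched or exceeded in 2 of the 35 splits, the real one included, and genes lower (23) also in 2, so chance could not be excluded by this count. The highest other split had 45 genes on one side and parted odd from even replicate numbers, which points to a structure of the samples. Sex moves with it, since the odd-numbered arrays hold 3 males and 1 female by their Y-linked genes and the even-numbered ones 1 male and 3 females, but the split of the 8 arrays by sex alone gave 3 genes higher and 3 lower. With odd or even number in the fit 33 genes were higher and 60 lower, and all 44 genes remained. For the 6 gene lists 20 of the 35 splits gave as many, with up to 16, so chance could not be excluded there.

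Data outside the main comparison were tested too. Among 13767 clusters with no symbol or several, 3 passed the threshold, all lower in Bcl6 cKO and all without a symbol. This was reached in 1 of the 35 splits, the real one, with 1 cluster as the highest of the others. That is the smallest share such a test can give, and the splits ignore the replicate numbers. No other split test came out this way, and their number was not corrected for, so chance was not excluded. The count fell to 0 with sex in the fit, with the replicate block and in 7 of the 8 fits without 1 array (2 without Bcl6 cKO replicate 1).

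Single arrays that stood apart from their group were looked for in 246 groups of 4 values, and 20 were found, where chance gives about 5%. The sex-linked genes account for 8 of them. The rest are about as many as chance gives, so they are listed without a claim. Wild-type replicate 4 had Kdm5d at 5.83, Uty at 4.88, Xist at 12.52 and a mean of the sex-linked list of 6.98, against 9.77 to 9.82, 9.47 to 9.68, 5.72 to 6.28 and a list mean of at least 8.97 on the other wild-type arrays. Bcl6 cKO replicate 1 had Kdm5d at 9.71, Uty at 9.60, Xist at 6.12 and a list mean of 9.04, against 5.31 to 5.83, 4.58 to 5.04, 12.44 to 12.59 and 6.86 to 6.97 on the others. Bcl6 cKO replicate 1 also stood apart in Nrp1 (7.54, others 8.03 to 8.08), Il6st (12.07, others 11.87 to 11.90), Klf1 (6.15, others 6.40 to 6.43) and Hsp90aa1 (13.01, others 13.10 to 13.11). Bcl6 cKO replicate 2 did so in Cxcr4 (7.97, others 7.66 to 7.69), Gzmb (8.63, others 7.40 to 7.48) and the mean of the dissociation stress list (10.07, others 9.88 at most). In wild type, replicate 2 stood apart in Bhlhe40 (10.57, others 10.22 to 10.27) and Gzmb (7.69, others 6.92 to 7.01), replicate 1 in Il6st (12.08, others 12.19 to 12.20), replicate 4 in Il17f (7.30, others 7.07 to 7.10) and replicate 3 in Ccl17 (6.79, others 6.70 to 6.71).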

How the results depend on the processing

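The settings with sex, with the first principal component of the residuals, with odd or even numbers, within each sex and without chromosomes were chosen after seeing the data; the rest were planned. A planned fit with a surrogate variable is not reported, since its package could not be used in the final run; the residual component, itself estimated from these values, stands in for it. Bcl6 stayed above 0 and short of the threshold under 20 other settings (log2 difference 0.27 to 0.57). The fits within each sex are not among them. The cause of the shifts below was not tested, except that fewer genes or arrays enter some fits. Genes higher and lower numbered 21 and 23 as reported. Genes lower were 61 with trend and robust moderation, 51 with array weights, 13 after median centring, 14 after quantile normalization, and 42 and 52 above the 30th percentile and the median of signal, filters that leave out Il1a and Atg4c. Both moved with the first principal component of the residuals (35 and 53), sex (5 and 5), odd or even number (33 and 60), sex with odd or even number (5 and 5), at least 1.5-fold (11 and 7), an adjusted p under 0.1 (42 and 90), within males (0 and 0, limma, 852 genes at an unadjusted p under 0.05) and within females (32 and 11). Without wild-type replicates 1 to 4 they were 6 and 5, 9 and 9, 8 and 10, and 7 and 5; without Bcl6 cKO replicates 1 to 4 they were 39 and 100, 12 and 10, 5 and 6, and 6 and 5. Gene lists past the threshold numbered 6, with 2 after quantile normalization, 0 with an estimated correlation, 0 with fry (1 unadjusted), and 4 to 8 without 1 array. The 3 clusters without a single symbol became 6 with trend and robust moderation, 6 with array weights, 0 with the replicate block, 0 with sex, and 0 without 1 array in turn, except 2 without Bcl6 cKO replicate 1.

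The labels number the samples 1 to 4 in both groups. Deviations from the group means correlated at 0.073, 0.206, 0.203 and 0.205 within numbers, and 6 of the 8 arrays correlated best with their own number, a hint from the data only. With the replicate block 15 genes were higher and 20 lower, of which 23 were among the 44, so 21 of the reported genes did not pass. Of the 7 lists that passed, 5 were among the 6 reported, amino acid and unfolded protein stress was lost, and the Th1 and cytotoxic and the interferon-stimulated lists were gained; with an estimated correlation none passed.

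Over the settings tallied, which leave out the fits within each sex, no sign turned for single genes and lists past the threshold. Of their values 262 for genes and 90 for lists stayed past it and 152 and 42 did not. In these settings signs turned only in genes and lists not past the threshold as reported. Within the arrays with high Y-linked signal the amino acid and unfolded protein stress list, past the threshold as reported, did turn, to -0.07. Without 1 array in turn, Klf1 ranged from -0.043 to 0.050, dissociation stress from -0.057 to 0.015, DNA damage from -0.037 to 0.026, interleukin-2 targets from -0.059 to 0.080, the early T cell receptor response from -0.114 to 0.042, and natural killer markers from -0.00108 to 0.042. DNA damage became 0.00162 after median centring and 0.00281 after quantile normalization. Interleukin-2 targets became -0.000145 with array weights, -0.00931 and -0.0451 with the 2 signal filters and -0.00667 with sex. With sex the early T cell receptor response became 0.0866 and natural killer markers -0.00567. The follicular helper list became -0.00315 above the 30th percentile of signal. With sex and odd or even number, Uty became 0.0075, memory markers 0.00117 and sex-linked genes 0.00375.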

Other observations

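The comparison of odd with even replicate numbers, and the genes named in these paragraphs, were chosen after the data were seen. Odd against even was also the split with the most genes on 1 side (45) apart from the real one. Its p-values are not corrected for a choice among splits.

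Of the 20 genes of the early T cell receptor list, which was fixed beforehand, 16 were higher and 4 lower in odd-numbered than in even-numbered samples, with genotype in the fit (fry adjusted p = 0.0123, and camera adjusted p = 0.194 with an estimated correlation). Of these 20, 9 passed a limma adjusted p of 0.05, all 9 higher in odd samples. It was the 1 list of 27 to pass with fry. Sex is unbalanced here as well, with 3 males and 1 female by Y-linked genes among the odd-numbered arrays and 1 male and 3 females among the even-numbered ones. With sex also in the fit the list no longer passed (fry adjusted p = 0.174, and camera adjusted p = 0.263 with an estimated correlation), and 4 of its genes passed alone, all 4 higher. With camera at the preset correlation and no other term, 10 of the 27 lists passed odd against even. Trafficking (-0.22), chemokine ligands (-0.23) and Th17 (-0.20), reported for genotype above, were among them. Proliferation, naive T cell and amino acid stress genes were not. With an estimated correlation and genotype in the fit the lowest adjusted p was 0.194. Over all genes, with genotype but not sex in the fit, 90 were higher and 43 lower on the 4 odd-numbered arrays (limma, adjusted p under 0.05). None of them was among the 44 genes that differed by genotype. This lack of overlap says little, since chance gives almost none with so few of 19938 genes called. The genotype fit also had no odd or even term, so genes that differ by it had a wide spread there. With sex also in the fit 32 were higher and 19 lower, and 47 of these 51 had passed without it. The single genes higher in odd samples included Nr4a2 (10.71 against 8.77 on average), Egr3 (11.16 against 10.39), Nr4a1 (12.93 against 12.21), Egr1 (11.08 against 10.50), Dusp6 (11.21 against 10.14), Ubash3b (10.78 against 9.63), Pdcd1 (log2 difference 0.81), Fasl (0.75) and Cd40lg (0.59). Those lower in odd samples included Gbp5 (9.63 against 10.60), Socs2 (10.40 against 11.35) and Irf1 (10.57 against 11.32). With sex in the fit Cd40lg did not pass (adjusted p = 0.0603), and the other named genes did. The labels do not say what the numbers mark.

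Several further genes past the threshold differed between the genotypes. The retinoid receptor gene Rxra rose from 9.24 ± 0.07 to 9.69 ± 0.09 (log2, SD, n = 4 each; limma adjusted p = 0.0218). Luzp1 rose from 7.83 ± 0.09 to 8.31 ± 0.05 and the mitochondrial complex I gene Ndufs5 from 8.95 ± 0.20 to 9.53 ± 0.04. The junction protein gene Jup (plakoglobin) fell from 7.94 ± 0.06 to 7.48 ± 0.06, Sun2 of the nuclear envelope from 10.36 ± 0.05 to 9.93 ± 0.11 and Lfng, a glycosyltransferase that modifies Notch, from 12.12 ± 0.03 to 11.77 ± 0.08. With sex in the fit none of these 6 passed (adjusted p from 0.0511 for Jup to 0.146 for Lfng and Sun2).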
